A study of Danio rerio with 3 samples.

How the data were processed

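Single-cell RNA sequencing was analysed for 3 libraries of zebrafish olfactory tissue, 1 each from embryos at 36, 48 and 72 hours post fertilization (hpf). The embryos carried Tg(omp:lyn-RFP), a transgene that places a membrane-bound red fluorescent protein (RFP) under the olfactory marker protein promoter, and RFP-positive cells were sorted by flow cytometry before capture. Per the labels' protocols the libraries were made with 10x Genomics chemistry, and each library was read in 2 sequencing runs. The deposited counts are unique molecular identifiers (UMIs) per gene and cell barcode, made with Cell Ranger 3.0.1 against GRCz11 per the submitters' processing notes and the file headers, with no normalization. The rule by which the authors kept barcodes is not given in the sources used here; the lowest total of any barcode was 500 UMIs. Each matrix held 27771 gene features, of which 1201 shared a symbol with another feature, so features with a shared symbol were kept apart by their Ensembl identifiers. No columns of per-sample values were left out. The reference genome at hand was of another build, so no coordinates are given.

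The gene lists, cell type markers, tests, rule for named genes and most alternatives were fixed before the data were examined. Cells with at least 1000 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library by the Scrublet procedure, with 2 simulated doublets per cell. Its automatic threshold marked under 0.5% of cells, so the threshold was set from the rate usual for this chemistry, 0.8% per 1000 cells. That rate was 3.11%, 6.13% and 4.09% of cells at 36, 48 and 72 hpf. Every cell at or above the score at that rank was removed, so equal scores raised the number, to 148, 479 and 227 cells. These calls made up 3.80%, 6.25% and 4.44% of the filtered cells, and 26.6%, 38.1% and 28.6% of simulated doublets scored above the same threshold, so most doublets stayed in. Counts were scaled per cell and log-transformed, and cells of all libraries were clustered together without batch correction, from 2000 variable genes, 40 principal components, 20 neighbours and the Leiden method at resolution 1.0. Delta and clustered protocadherins, other cadherins, guidance receptors and ligands, other adhesion genes and all chemoreceptor genes were held out of clustering, so that no class was defined by them.

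Clusters were named from the fixed markers, a marker counting as raised at a fold of 2 over the remaining cells with a prior of 10 CPM. A name needed at least 3 raised markers, 33.3% of its list, and no other list with more members among the 10 leading genes. Clusters in which at least 50% of cells had 3 or more ciliated olfactory sensory neuron (OSN) markers formed an olfactory neuron region and were clustered again with 30 principal components. The rules within it were set after the clusters were seen. Clusters with krt4 at 1000 CPM or more were kept out and called keratin-high with OSN markers where ompb reached 100 CPM. Subclusters of the region were microvillous OSN-like with 3 raised microvillous markers, mature ciliated OSN-like with ompa plus ompb at 0.65 of the region's mean level or more, and immature OSN-like with at least 4 raised immature neuron markers. "OSN-like" means mature ciliated and immature OSN-like cells together. No deposited cell annotation was used, so names and shares rest on this clustering.

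There was 1 library per age, so differences between ages have no replicate check and no p-value, standard error or count of changed genes is given for them. UMIs were summed over OSN-like cells per library and given as CPM over those UMIs. Levels carry exact Poisson intervals, shares exact Clopper-Pearson intervals and log2 ratios exact conditional binomial intervals, all at 95% and all covering counting error only. A count of 0 allows up to 3 counts. Changes of a gene list between ages are medians of log2 ratios over members at 5 CPM or more in at least 1 library, with a pseudocount of 1 CPM, given with the percentile of the median among 10000 random lists matched on mean expression in 20 bins. The percentile describes these libraries. The trimmed mean of M-values (TMM) scaling would shift every log2 ratio by -0.06 for 48 over 36 hpf, 0.14 for 72 over 48 hpf and 0.08 for 72 over 36 hpf.

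The lists were the delta1 protocadherins (9 features), delta2 protocadherins (7 features), clustered protocadherins, other cadherins, axon guidance receptors, axon guidance ligands, other axonal adhesion genes, olfactory receptor (OR) genes (140 features), trace amine-associated receptors (94 features), the olfc and ora vomeronasal-type receptors (56 features), ciliated OSN transduction, immature OSN and axon growth, neurogenic factors, OSN transcription factors, presynaptic genes, cell cycle, cilium assembly, immediate early and dissociation stress genes, cytosolic ribosomal proteins, mitochondrial transcripts and nuclear oxidative phosphorylation genes. By age the text could name every delta protocadherin with at least 10 UMIs in any library, up to 4 genes per other list with the largest absolute log2 ratio of 72 over 36 hpf at 20 CPM or more, and the 8 highest and 8 lowest ratios among all genes at 50 CPM or more whose 48 hpf level lay between the other ages. That last part left out mitochondrial, ribosomal protein and receptor genes and genes named only by a clone or locus. In tested contrasts it could name every delta protocadherin, up to 4 genes past the threshold per other held-out list by size of fold change, and up to 5 further genes per OR family and direction with a mean of at least 20 CPM. Any other gene is said to have been chosen after its values were seen.

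Contrasts between cell classes were tested on UMIs summed per library and class, 6 sums per contrast, with edgeR's quasi-likelihood test, TMM factors, the filterByExpr filter and the library as a block. The threshold was an adjusted p of 0.05 after Benjamini-Hochberg adjustment over all genes tested, and counts adjusted over the list alone are given beside those over all genes. The 3 libraries, which differ in age, stood in as replicates of a contrast shared by all ages. P-values therefore measure only the spread between these libraries, and cells were never used as replicates. OSN-like cells were set against all other cells, and mature ciliated against immature OSN-like cells; microvillous against ciliated OSN-like cells was added after the data were seen. Fold changes are log2 with standard errors taken from the test statistic.

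An OSN-like cell was assigned to an OR family, the number before the hyphen in the receptor symbol, if it had at least 2 OR UMIs and at least 80% of them came from that family. The 10 families with most cells among those with at least 20 cells in each library were each tested against cells of all other families, with OR genes left out of the calls. Families numbered 12 for the profile test, in which log2 CPM with a pseudocount of 5 CPM was centred per gene over families, for delta protocadherins at 5 CPM or more. The Pearson correlation over family and gene values was averaged over the 3 pairs of libraries and set against 100000 permutations of the family labels. Receptors and delta protocadherins per cell were counted in mature ciliated OSN-like cells after thinning each cell to 2000 UMIs. Co-detection of 2 delta protocadherins was an odds ratio with 0.5 added to each cell of the table, for genes seen in at least 30 cells per library.

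The tests were run on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. All simulated genes shared 1 dispersion, and the means held no difference between libraries. Changed genes were drawn only from those above a floor of total UMIs. In the real contrast of OSN-like against other cells far more genes passed than were changed here. The rates below therefore describe these simulated settings and not the real fits. With edgeR's quasi-likelihood test 63.6% of 2-fold and 94.0% of 4-fold changes were recovered for OSN-like against other cells over 17831 genes with 1 false call, and 71.7% and 98.0% for mature against immature cells over 12069 genes with 4 false calls. Recovery was 53.0% and 94.9% for the or137 family over 9994 genes with 4 false calls, and 30.6% and 66.3% for the smaller or110 family over 10072 genes with 4 false calls. For microvillous against ciliated cells it was 81.8% and 100% over 12243 genes with 10 false calls. No simulated gene was called with the wrong sign.

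Alternatives were a looser cell filter, no doublet removal, Leiden resolutions 0.5 and 2.0, clustering each library alone, OSN-like cells defined per cell by detected markers, TMM scaling, thinning, DESeq2 or its size factors, no low-count filter, no library block, each library left out, other OR thresholds, a higher expression floor and another pseudocount. Mature cells alone for summed delta protocadherins by age, other cells without the keratin-high clusters, mature and immature cells without UMIs of the microvillous markers trpc2a, trpc2b or vmn2r1, and the microvillous contrast with its own alternatives were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.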

Results

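The series asks how delta protocadherins, homophilic adhesion molecules of the cadherin superfamily, take part in the targeting of olfactory sensory neuron (OSN) axons to protoglomeruli, the early axon targets in the zebrafish olfactory bulb. Gene expression was measured in single cells sorted for red fluorescence from Tg(omp:lyn-RFP) embryos, whose OSNs carry a membrane-bound red fluorescent protein. There was 1 library at each of 36, 48 and 72 hpf, pooled from roughly 2000 embryos in all, and ages throughout are those on the labels. The files held 4748, 11057 and 5913 cell barcodes at 36, 48 and 72 hpf, with 72966819, 140555599 and 98942869 UMIs. Median depth was 10235.5, 7619 and 10267 UMIs per barcode, and 2768.5, 2183 and 2819 genes were detected. After filtering and removal of called doublets 3744, 7189 and 4890 cells remained, with a median of 12562.5, 11015 and 12212.5 UMIs. Differences between ages rest on 1 library each, have no replicate check and were not tested, and age cannot be told apart from library. All intervals are 95% and cover counting error only.

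OSN-like cells, defined by markers such as ompb, cnga4 and gnal, made up 31.1% (29.6 to 32.6) of cells at 36 hpf, 21.3% (20.3 to 22.2) at 48 hpf and 28.8% (27.5 to 30.1) at 72 hpf, or 1164, 1529 and 1408 cells. Immature OSN-like cells, led by neuronal growth genes, were 11.2% (9.42 to 13.1), 2.03% (1.38 to 2.87) and 8.38% (6.99 to 9.95) of OSN-like cells. Microvillous OSN-like cells, which carry the trpc2b channel, were 5.61%, 2.77% and 4.72% of all cells. Cells with both periderm keratins and OSN transcripts, kept out of the OSN-like class by a threshold set after the data were seen, were 26.9%, 16.3% and 32.0%. Further subclusters with OSN markers were left out because genes of other cell types led them (2.78%, 1.73% and 1.41%) or because no name fitted (3.13%, 2.48% and 4.85%). Central nervous system neuron-like cells were 3.53%, 14.1% and 4.15%, but 1 of their clusters, led by pax10, tfap2a and tfap2b, held 0, 350 and 6 cells at 36, 48 and 72 hpf. Further cells were macrophage-like, at 0.481%, 7.78% and 0.348%. The sort for red fluorescence preceded every library and sets these shares in part. Within the ciliated class different subclusters held most cells of each library: number 1 at 36 hpf with 826 cells, number 0 at 48 hpf with 953, and numbers 3 and 2 at 72 hpf with 441 and 367. Median depth of OSN-like cells was 6726.5, 5695 and 5718 UMIs, and the class summed to 10836859, 11101244 and 10867146 UMIs.

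The comparison by age asked which delta protocadherins OSNs express while their axons reach the bulb. Transcripts of all 16 delta protocadherin features summed to 691 CPM (675 to 707) in OSN-like cells at 36 hpf, 665 CPM (650 to 680) at 48 hpf and 604 CPM (590 to 619) at 72 hpf. The most abundant was pcdh7b, a delta1 member, at 199, 187 and 158 CPM, or 28.8%, 28.2% and 26.1% of all delta protocadherin UMIs. The delta2 member pcdh19, which acts together with N-cadherin in adhesion, followed at 105, 94.9 and 92.3 CPM. Both features that share the symbol pcdh11 lay close behind, ENSDARG00000098652 at 80.8, 64.1 and 65.2 CPM and ENSDARG00000105441 at 73.5, 77.1 and 79.9 CPM. Their sequences were not compared, and whether they stand for separate genes was not tested. The delta2 members pcdh10b and pcdh17 stood at 75.9, 73.7 and 62.2 CPM and at 46.9, 64.0 and 55.9 CPM. At lower levels pcdh18b had 30.6, 52.2 and 33.2 CPM, pcdh18a 24.0, 18.3 and 15.9 CPM, pcdh7a 17.8, 8.02 and 12.6 CPM, pcdh1b 16.1, 8.92 and 14.999 CPM, and pcdh9 11.6, 5.86 and 8.56 CPM. The remaining members, pcdh10a, pcdh8, pcdh1a and both pcdh20 features, were under 5 CPM in each library.

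As log2 ratios, the summed delta protocadherins stood at -0.06 (-0.10 to -0.01) for 48 over 36 hpf, -0.14 (-0.19 to -0.09) for 72 over 48 hpf and -0.19 (-0.24 to -0.15) for 72 over 36 hpf. With TMM scaling the 72 over 48 hpf ratio was 0.0009, so no direction is given for it. Among members at 5 CPM or more the largest single ratios for 48 over 36 hpf were pcdh7a at -1.15, pcdh9 at -0.99, pcdh1b at -0.85 and pcdh18b at 0.77; their ratios for 72 over 48 hpf were 0.65, 0.55, 0.75 and -0.65. The ratios of pcdh17 were 0.45 and -0.19. Over the 6 delta1 features at 5 CPM or more the median ratio was -0.56 for 48 over 36 hpf, at the 0.19th percentile of random lists, and 0.26 for 72 over 48 hpf, at the 99.8th. Over the 5 delta2 features it was -0.04 and -0.19, at the 49.9th and 12.4th percentiles. With members at 20 CPM or more the delta1 medians were -0.09 and 0.02.

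**Figure D1:**
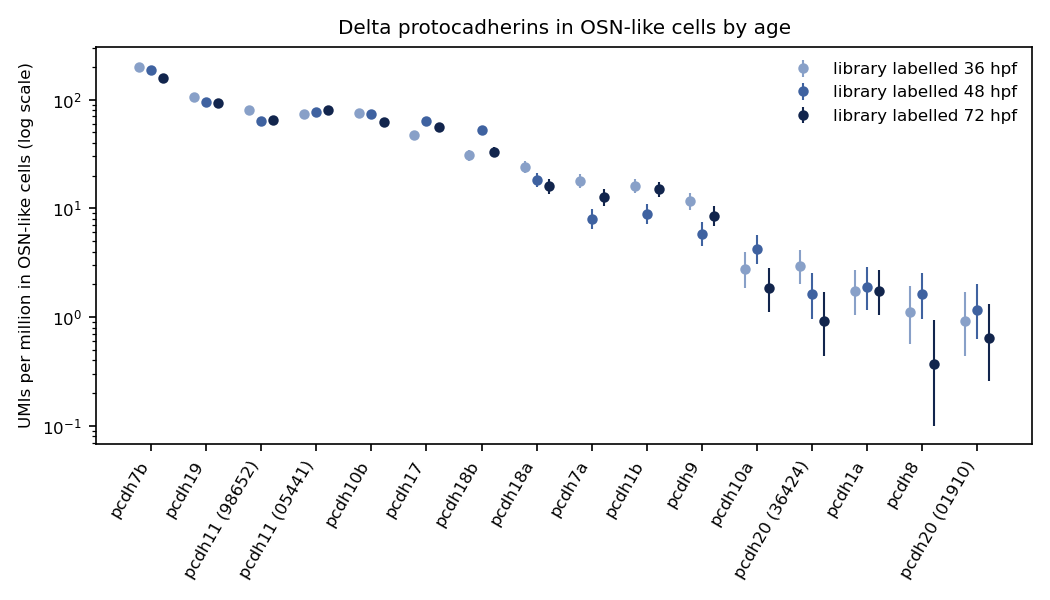
Expression of the 16 delta protocadherin features in OSN-like cells at 36, 48 and 72 hpf, 1 library each, as CPM on a log scale with exact Poisson 95% intervals for counting error. The gene pcdh7b is highest in each library, at 199, 187 and 158 CPM, and pcdh19 follows at 105, 94.9 and 92.3 CPM.

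In single cells thinned to 2000 UMIs, pcdh7b was detected in 32.3%, 26.6% and 24.1% of OSN-like cells at 36, 48 and 72 hpf, against 67.3%, 55.4% and 53.9% before thinning. For pcdh19 the thinned shares were 18.5%, 15.3% and 15.9% (46.6%, 35.6% and 38.3% before thinning), and for pcdh10b 11.3%, 11.1% and 10.18% (29.98%, 29.3% and 25.4%). Detection of pcdh17 was 6.71%, 8.72% and 9.54% (19.2%, 23.5% and 22.6%). Macrophage-like cells of the 48 hpf library, a blood lineage without known use of these genes, gave 0.537% for pcdh7b, 0.895% for pcdh19, 0.358% for pcdh10b and 0.537% for pcdh17 at the same depth, and 4.83%, 7.16%, 5.01% and 3.04% before thinning. They had a median of 26462 UMIs over 559 cells, above the 5695 UMIs of OSN-like cells. Thinning left out 2, 4 and 3 OSN-like cells with fewer UMIs.

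Other genes of axon guidance and adhesion were compared by age in OSN-like cells as well. The chemokine receptor cxcr4b, which guides olfactory placode cells and axons, had 189, 39.2 and 108 CPM at 36, 48 and 72 hpf, and the semaphorin coreceptor nrp2b 43.5, 16.6 and 29.4 CPM. The plexin plxnb1a had 21.04, 10.4 and 10.95 CPM. The 22 guidance receptors measured had a median log2 ratio of -0.37 for 48 over 36 hpf, at the 0.02th percentile of random lists, and of 0.11 for 72 over 48 hpf, at the 99.9th. Among 16 guidance ligands, bdnf, a neurotrophin, had 308, 196 and 263 CPM and the semaphorin sema4ab 49.2, 74.8 and 62.02 CPM; the list's medians were 0.09 and -0.07, at the 67.9th and 65.5th percentiles. The 32 other adhesion genes had medians of -0.25 and -0.03, at the 0.18th and 78.5th percentiles, with the immunoglobulin-family gene dscama at 154, 95.1 and 108 CPM. For 9 other cadherins the medians were -0.30 and 0.04, with N-cadherin cdh2 at 119, 82.2 and 90.4 CPM and cdh6 at 32.6, 61.5 and 44.6 CPM. The 5 clustered protocadherins had medians of -0.61 and -0.08, and the most abundant, pcdh2g28, had 37.4, 39.2 and 37.1 CPM. The negative 72 over 48 hpf medians of guidance ligands, other adhesion genes and clustered protocadherins lay within the TMM shift of 0.14, so they give no direction. The share of immature cells among OSN-like cells, 11.2%, 2.03% and 8.38%, differed between the same libraries.

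Markers of OSN identity and maturity set the library labelled 48 hpf apart. Over 83 OR genes, the receptors that give each OSN its odour response, the median log2 ratio was 2.21 for 48 over 36 hpf, with 69 genes higher and 14 lower, and -1.11 for 72 over 48 hpf, at the 100th and 0th percentiles. Over all OR UMIs together the ratios were smaller, 0.71 (0.70 to 0.73) and -0.44 (-0.45 to -0.43). The receptor or125-3 had 7.11, 110 and 53.9 CPM, and or106-2 had 5.35, 78.6 and 66.2 CPM. The 9 trace amine-associated receptors had medians of 2.36 and -1.996, with taar13b at 14.6, 43.1 and 19.2 CPM. Of the olfc and ora list only ora1 and ora3, chosen after their values were seen, passed 5 CPM in any library, at 10.15, 2.34 and 4.23 CPM and at 8.12, 0.991 and 5.61 CPM. A subcluster led by taar13b, with 0.0267%, 1.57% and 1.43% of cells, stood outside the OSN-like class. So did a subcluster led by ora3, with 2.38%, 0.737% and 2.66%. The taar and ora levels given here leave out the cells of these subclusters. Among 14 genes of ciliated OSN transduction, which helped to define the class, 13 were higher at 48 than at 36 hpf (median 0.22) and 12 lower at 72 than at 48 hpf (median -0.21); ompb had 532, 1142 and 843 CPM and gnal, the olfactory G protein subunit, 1248, 2095 and 1796 CPM. The 25 genes of immature OSNs and axon growth had a median of -0.58 for 48 over 36 hpf, with 22 lower, and 0.27 for 72 over 48 hpf, with 17 higher. Of these marcksb, a growth cone substrate of protein kinase C, had 289, 94.0 and 153 CPM and stmn4, a microtubule destabilizer, 78.6, 44.0 and 29.4 CPM.

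Transcription factors of the OSN lineage (39 genes) had medians of -0.40 for 48 over 36 hpf, with 30 lower, and 0.13 for 72 over 48 hpf. Placodal and forebrain regulators led them, with emx2 at 89.9, 20.4 and 40.03 CPM, dlx3b at 104, 32.4 and 52.5 CPM and pax6a at 83.1, 31.3 and 39.0 CPM. The 25 neurogenic factors had medians of 0.26 and -0.31, although neurod1, a proneural factor, had 36.9, 19.998 and 12.98 CPM and sox11b 90.5, 43.6 and 40.4 CPM. Presynaptic and neuronal genes (38) had medians of -0.29 and 0.10, with the intermediate filament inab at 38.1, 8.29 and 15.3 CPM and the glutamate transporter slc17a6b at 484, 316 and 313 CPM. For 24 cell cycle genes the medians were 0.57 and -0.47, with mki67 at 16.7, 25.3 and 19.4 CPM. The 55 cilium assembly genes had medians of 0.08 and -0.08, the latter within the TMM shift of 0.14.

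Stress and metabolic genes also differed between the libraries. Among 37 immediate early and dissociation stress genes 26 were higher at 48 than at 36 hpf (median 0.67, 100th percentile). Their median for 72 over 48 hpf was -0.09, within the TMM shift of 0.14. The heat shock genes hsp70l and hsp70.1 had 4579, 7558 and 9847 CPM and 420.4, 1332 and 1695 CPM, and the AP-1 member junbb 24.6, 108 and 90.9 CPM. Of 89 ribosomal protein genes 66 were lower at 48 than at 36 hpf (median -0.37) and 78 higher at 72 than at 48 hpf (median 0.20), but rpl26 had 15.04, 236 and 247 CPM. All 13 mitochondrial transcripts were higher at 48 than at 36 hpf (median 0.36), and their median for 72 over 48 hpf was -0.21. Nuclear oxidative phosphorylation genes (77) had a median of 0.35 for 48 over 36 hpf, with 66 higher, and 0.26 for 72 over 36 hpf, with 69 higher; for 72 over 48 hpf it was -0.09, and 0.05 with TMM scaling. Among all genes whose 48 hpf level lay between the other ages, the highest ratios of 72 over 36 hpf were those of large2, a glycosyltransferase of dystroglycan, at 10.4, 74.9 and 97.1 CPM and the metal-binding mt2 at 19.0, 93.8 and 94.7 CPM. The lowest included the glycolytic enzyme pgk1 at 193, 89.9 and 84.5 CPM and the antiproliferative btg3 at 60.5, 39.4 and 27.5 CPM.

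To ask which delta protocadherins mark OSNs among the sorted cells, OSN-like cells were set against all other cells of the same library. Both pcdh11 features were higher in OSN-like cells, ENSDARG00000105441 by 1.37 ± 0.10 (log2, SE, 3 libraries) and ENSDARG00000098652 by 1.24 ± 0.10, as were pcdh7b by 1.11 ± 0.13, pcdh18a by 0.70 ± 0.16 and pcdh17 by 0.56 ± 0.11. Lower were both pcdh20 features, at -4.45 ± 0.26 for ENSDARG00000101910 and -2.19 ± 0.27 for ENSDARG00000036424, and pcdh1a (-1.995 ± 0.21), pcdh10a (-1.71 ± 0.27) and pcdh1b (-0.58 ± 0.16). For pcdh7b this meant 199, 187 and 158 CPM in OSN-like cells against 87.3, 61.7 and 69.5 CPM elsewhere. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 10 of 16 delta features passed, 5 in each direction, with adjusted p from 0.00012 to 0.0212, and 10 passed when adjusted over the list alone. The other 6 had log2 fold changes of -2.24 (pcdh8), -0.64 (pcdh7a), -0.13 (pcdh9), 0.14 (pcdh18b), 0.18 (pcdh19) and 0.19 (pcdh10b). Each called feature had the same direction in 3 of 3 libraries. Without the 72 hpf library the calls of pcdh17 (0.45, adjusted p 0.0854) and pcdh1b (-0.63, adjusted p 0.0814) ended, and without the 36 hpf library pcdh7a (-0.93, adjusted p 0.0214) and pcdh8 (-3.39, adjusted p 0.00182) passed. With the keratin-high cells taken out of the other cells pcdh17 (0.41), pcdh18a (0.38) and pcdh1b (-0.02) no longer passed, while pcdh10b (0.64, adjusted p 0.0107) and pcdh8 (-2.73, adjusted p 0.0474) did. With OSN-like cells defined per cell by 3 detected ciliated markers, which takes in most keratin-high and microvillous cells, the direction turned for 6 of the 10, namely both pcdh20 features (2.01 and 0.54), pcdh1a (0.45), pcdh1b (0.995), pcdh17 (-0.28) and pcdh18a (-0.82), of which pcdh20 (ENSDARG00000101910) and pcdh1b passed the test in the opposite direction.

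Of all 211 held-out genes tested in this contrast 55 were higher and 89 lower in OSN-like cells, and 146 passed when adjusted over the list alone. Clustered protocadherins gave 7 higher, none lower and 25 not past the threshold, with pcdh2ab12 at 1.45. Other cadherins gave 3 higher and 14 lower of 24, among the latter celsr1b, a planar polarity cadherin, at -4.08. Guidance receptors gave 8 higher and 24 lower of 44, with the ephrin receptor epha2a at -4.31, or 3.69, 2.52 and 2.02 CPM against 58.0, 33.3 and 49.8 CPM; with the per-cell definition the log2 fold change of epha2a, OSN-like against other cells, was 0.66 and did not pass, nor did that of pcdh2ab12. Guidance ligands gave 9 higher and 30 lower of 45; the chemokine cxcl12b had at most 0.270 CPM in OSN-like cells against 6.28, 2.29 and 2.19 CPM elsewhere. Other adhesion genes gave 23 higher and 16 lower of 50, with alcama, an immunoglobulin-family adhesion molecule, at -3.04 and chl1a at -3.77. Over all 18053 genes tested 11025 passed.

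Maturation was addressed by setting mature ciliated against immature OSN-like cells of the same library. The immature class also held cells with microvillous transcripts: UMIs of trpc2a, trpc2b or vmn2r1 were found in 30.8%, 9.68% and 17.8% of immature cells at 36, 48 and 72 hpf, against 1.35%, 2.67% and 2.4% of mature ciliated and 77.1%, 80.4% and 73.6% of microvillous cells. Mature cells had more pcdh18b (2.30 ± 0.25, log2 with SE, 3 libraries), pcdh19 (1.22 ± 0.13), pcdh7b (1.06 ± 0.15) and both pcdh11 features, ENSDARG00000105441 (0.94 ± 0.17) and ENSDARG00000098652 (0.87 ± 0.13). Immature cells had more pcdh1a (-2.37 ± 0.56), pcdh7a (-1.66 ± 0.21), pcdh17 (-0.996 ± 0.13) and pcdh9 (-0.82 ± 0.25). In CPM pcdh18b had 37.6, 53.8 and 36.7 in mature against 4.38, 10.1 and 11.5 in immature cells, and pcdh17 had 41.4, 60.5 and 50.2 against 67.5, 158 and 92.3. These 9 of 14 delta features passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 1.11e-05 to 0.0234, and 10 passed when adjusted over the list alone. Values for the rest were 0.07 for pcdh1b, -0.22 for pcdh10b, 0.19 for pcdh18a, -1.22 for pcdh10a and -0.54 for pcdh20. The calls of pcdh1a (-1.47, adjusted p 0.199) and pcdh9 (-0.62, adjusted p 0.28) ended without the 72 hpf library, and that of pcdh9 also without the 36 hpf library (-0.97, adjusted p 0.0965). Low counts kept pcdh8 out of the test over 3 libraries; it passed as lower in mature cells without the 72 hpf library (-3.13, adjusted p 0.00396) and with no low-count filter (-2.70, adjusted p 0.00459). Without the 48 hpf library, which had only 31 immature cells, pcdh10a (-1.47) and pcdh10b (-0.40) passed as well. Without cells that had such microvillous UMIs, an alternative chosen after the data were seen, pcdh1a (-2.29, adjusted p 0.0194), pcdh7a (-1.43, adjusted p 0.000891) and pcdh17 (-1.24) passed and pcdh9 (-0.61, adjusted p 0.186) did not, while pcdh10a did (-1.74). Of microvillous cells 48, 39 and 61 had no such UMI, so cells of that kind can remain.

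Among 142 held-out genes tested here 21 were higher and 40 lower in mature cells, and 65 passed when adjusted over the list alone. The ephrin receptor epha6 was the guidance receptor with most transcripts among those named, 73.9, 72.4 and 76.7 CPM in mature against 15.3, 22.6 and 28.3 CPM in immature cells (1.77 ± 0.17). Guidance receptors gave 2 higher and 8 lower of 29, with the netrin receptor unc5c at -2.59. Guidance ligands gave 6 higher and 9 lower of 25, with slit1b, a repellent for Robo-bearing axons, at -4.26 and sema3gb at -3.64. Other adhesion genes gave 7 higher and 11 lower of 41, among the latter kirrel3l at -3.71, the teneurin tenm3 at -2.96 and dscaml1 at -4.85. Other cadherins gave 1 higher and 7 lower of 15, with dchs1a at -3.73, and of 18 clustered protocadherins only pcdh2g28 passed, at -0.79. Over all 12416 genes tested 4254 passed.

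**Figure D2:**
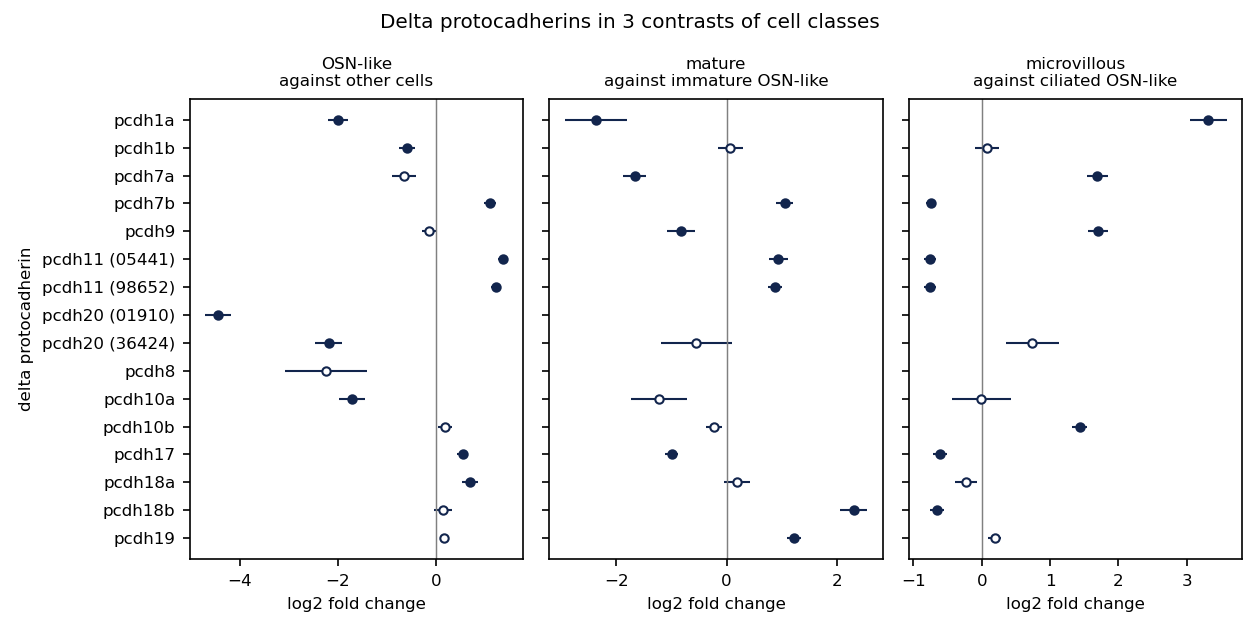
Log2 fold changes with standard errors of delta protocadherins in 3 contrasts, OSN-like against other cells, mature against immature OSN-like cells and microvillous against ciliated OSN-like cells, each over 3 libraries; filled points have an adjusted p under 0.05. The gene pcdh7b is at 1.11, 1.06 and -0.75 and pcdh17 at 0.56, -0.996 and -0.61.

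Because OSNs that express related receptors send axons to shared protoglomeruli, delta protocadherins were compared between cells assigned to different OR families. A family could be assigned to 652, 986 and 766 cells at 36, 48 and 72 hpf, or 66.7%, 74.0% and 64.4% of cells with at least 2 OR UMIs. Cells of or110, or120 and or129 each held a single receptor of their family, or110-2, or120-1 and or129-1. Most or109 cells were led by or109-11 (65, 40 and 56 cells) and most or137 cells by or137-8 (91, 63 and 93 cells). Most or128 cells were led by or128-10 (49, 24 and 52 cells) and most or132 cells by or132-5 (29, 29 and 27 cells). For these families, values of the family and of 1 receptor cannot be told apart. In or125, with 109, 56 and 98 assigned cells, or125-4 led 87, 27 and 64. Values of or125 thus also rest largely on 1 receptor at 36 and 72 hpf. The delta2 member pcdh10b was higher in cells of the or110 (1.54 ± 0.18, log2 with SE, 3 libraries), or125 (1.44 ± 0.15) and or115 (1.13 ± 0.16) families and lower in or129 (-2.96 ± 0.34), or120 (-2.70 ± 0.44) and or128 (-1.62 ± 0.25). In or110 cells it had 209, 224 and 157 CPM against 69.3, 64.0 and 54.1 CPM in other assigned cells. The delta2 member pcdh17 was higher in or109 (1.23 ± 0.17), or132 (1.17 ± 0.19) and or111 (1.16 ± 0.18) and lower in or129 (-3.46 ± 0.40), or137 (-3.35 ± 0.36), or128 (-2.67 ± 0.36) and or125 (-2.13 ± 0.28). The delta1 gene pcdh11 (ENSDARG00000105441) was higher in or129 (1.74 ± 0.13), or132 (1.40 ± 0.15) and or137 (1.19 ± 0.11), reaching 198, 234 and 239 CPM in or129 against 69.3, 70.06 and 64.0 CPM, and lower in or125 (-1.52 ± 0.16) and or128 (-1.52 ± 0.24). The other pcdh11 feature, ENSDARG00000098652, had 1.64, 1.26 and 1.49 in the former and -1.21 and -1.61 in the latter families.

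Other members had narrower patterns. The gene pcdh1b was higher in or128 (2.39 ± 0.30) and or125 (1.68 ± 0.27) and had 0 UMIs in or137 cells of each library, against 16.5, 8.44 and 16.6 CPM in other assigned cells. For pcdh19 the higher family was or125 (0.87 ± 0.11), for pcdh7a or129 (2.26 ± 0.31) and for pcdh18b or137 (1.01 ± 0.16), while pcdh7b was lower in or109 (-0.96 ± 0.14) and or125 (-0.86 ± 0.12). The difference of pcdh7a lay at 36 and 72 hpf, with 82.1 and 46.7 CPM in or129 against 13.2 and 8.14 CPM. At 48 hpf or129 cells had 9.90 CPM of pcdh7a against 8.42 CPM. No family passed for pcdh18a in 10 tested or for pcdh10a in 1 tested. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes of each family, 55 of 111 pairs of delta feature and family passed, 22 higher and 33 lower, and 71 passed when adjusted over the list alone. The adjusted p of pcdh10b in or110 was 1.03e-10 and that of pcdh11 (ENSDARG00000105441) in or129 was 1.64e-13. Counts of higher and lower families out of 10 were 4 and 5 for pcdh10b and 3 and 6 for pcdh17. They were 3 and 6 for pcdh11 (ENSDARG00000105441) and 3 and 5 for the other pcdh11 feature. For pcdh1b they were 3 and 3, for pcdh7b 2 and 4, and for pcdh19 1 and 4. Calls of both pcdh11 features are counted in the 55, and whether these are separate genes was not tested. The 55 calls became 43, 51 and 46 without the 36, 48 or 72 hpf library, 36 with DESeq2 and 12 without the library block.

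Some of these calls ended when 1 library was left out. For pcdh10b in or109 (0.58 ± 0.16, adjusted p 0.0403 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) the value was 0.51 without 36 hpf and 0.29 without 48 hpf, and at 72 hpf or109 cells had 44.3 against 59.0 CPM in other assigned cells. For pcdh1b in or120 (2.15 ± 0.40) it was 1.87 without 36 hpf. For pcdh9 in or129 (1.41 ± 0.41) it was 1.24 without 48 hpf and 1.104 without 72 hpf, and for pcdh17 in or120 (-2.26 ± 0.48) -2.43 without 36 hpf and -1.61 without 72 hpf. The value of pcdh19 in or128 (-1.37 ± 0.25) was -0.72 without 36 hpf, that of pcdh10b in or132 (-1.43 ± 0.26) -1.12 without 36 hpf, and that of pcdh7b in or128 (0.65 ± 0.12) 0.58 without 72 hpf. DESeq2 did not call pcdh10b in or109 and or132, pcdh17 in or120, pcdh19 in or128 or pcdh9 in or129.

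**Figure D3:**
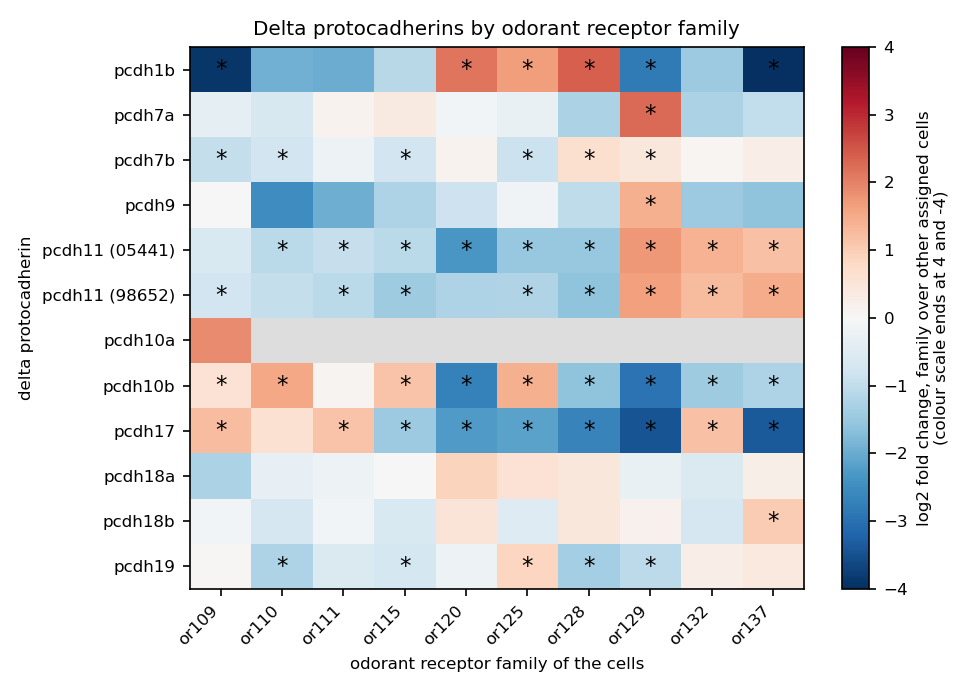
Log2 fold changes of 12 delta protocadherin features (rows) in cells of each of 10 OR families (columns) against all other assigned cells; stars mark an adjusted p under 0.05, grey fields were not tested, and the colour scale ends at 4 and -4. Values of pcdh1b in or137 and or109, where 0 UMIs were found in most libraries, depend on the prior count of the fit; pcdh10b reads 1.54 in or110 and -2.96 in or129.

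Guidance and adhesion genes outside the protocadherins differed between the same families. The semaphorin coreceptor nrp2b was higher in or120 (1.63), or125 (1.24) and or128 (1.04) and lower in or137 (-3.995), or129 (-3.20), or110 (-2.62), or109 (-2.29) and or111 (-1.41). The teneurin tenm4 was higher in or110 (1.68), or115 (1.33), or125 (0.94) and or109 (0.61) and lower in or129 (-2.93), or120 (-1.86), or128 (-1.535), or132 (-1.17) and or137 (-0.92). The ephrin efna3a was higher in or109 (0.90) and lower in or137 (-3.13), or129 (-2.54) and or132 (-1.72). The secreted semaphorin sema3fa was higher in or137 (2.36) and lower in or129 (-1.74), or125 (-1.53) and or128 (-1.14), and epha6 was higher in or128 (1.18) and or129 (1.17) and lower in or115 (-1.93), or109 (-1.05), or110 (-1.03) and or111 (-0.79). The axon repellent slit2 was higher in or110 (1.59) and or115 (1.53) and lower in or129 (-2.44) and or137 (-1.98). Outside the lists genes that were higher in at least 1 family included crybg1b in or132 (3.96), afap1l1a in or129 (3.91), nell2b in or132 (3.355), the transcription factor atf5b in or110 (3.203), tmeff2a in or137 (3.17), the calcium-binding protein calb2a in or125 (2.03), the arrestin arrb1 in or125 (2.93), the G protein regulator rgs8 in or128 (2.19) and the orphan nuclear receptor nr4a3 in or137 (2.99). The neural transcription factor olig2 was lower in or137 (-3.88), or129 (-3.04) and or132 (-2.25), and the hormone gene rln1 was lower in 8 families, from -1.52 in or115 to -5.31 in or132. Several of these genes also passed in the opposite direction in other families, of which 1 per gene is given here, chosen after the values were seen: arrb1 was lower in or129 (-7.905), atf5b in or129 (-3.285), crybg1b in or111 (-3.125), tmeff2a in or120 (-3.005), nr4a3 in or109 (-2.08), calb2a in or129 (-2.09) and rgs8 in or132 (-1.67), and olig2 was higher in or109 (0.71). All these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over the 10 families 2329 pairs of gene and family passed, from 61 in or111 to 652 in or129. That count was 1529, 2820 and 1241 without the 36, 48 or 72 hpf library, 964 with DESeq2, 128 without the library block, and 1003 when all OR UMIs of a cell had to come from the family.

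The next question was whether an OR family kept its delta protocadherin profile from library to library. Across 12 families and 11 delta features the centred log2 levels correlated with r = 0.645 between 36 and 48 hpf, 0.730 between 36 and 72 hpf and 0.738 between 48 and 72 hpf, with a mean of 0.704. In 100000 permutations of the family labels the highest mean was 0.367, and the permutation p, over 12 families, was 1e-05, the smallest these permutations can give. By gene pcdh10b had r = 0.849, 0.864 and 0.865 over the families and pcdh7b 0.826, 0.835 and 0.948 for the same pairs of libraries. For pcdh18a r was 0.402, 0.151 and 0.024, and for pcdh7a -0.158, 0.640 and 0.084. These values are across families and genes, which are not independent replicates. Both pcdh11 features are among the 11.

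**Figure D4:**
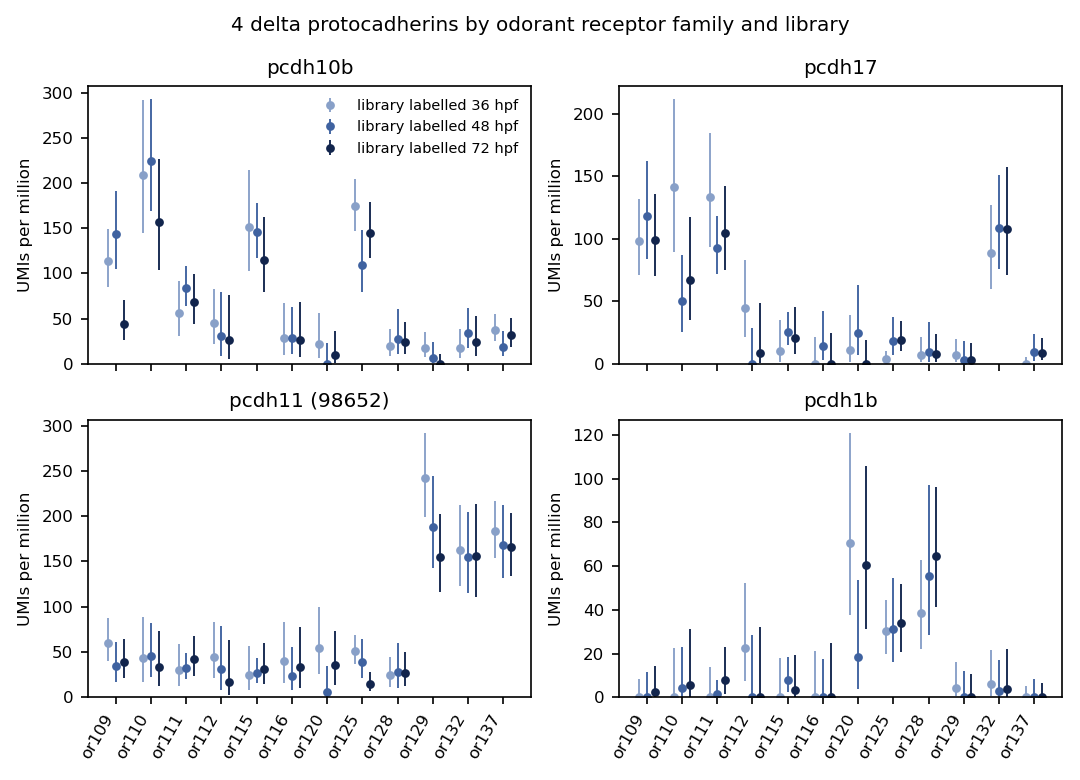
Levels of pcdh10b, pcdh17, pcdh11 (ENSDARG00000098652) and pcdh1b in cells of 12 OR families, as CPM with exact Poisson 95% intervals for counting error, with 1 point per library at 36, 48 and 72 hpf. Cells of or110 have 209, 224 and 157 CPM of pcdh10b, and or129 cells have 17.8, 6.60 and 0 CPM.

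Receptor choice was described in mature ciliated OSN-like cells thinned to 2000 UMIs. More than 1 OR gene was detected in 42.6%, 43.6% and 47.7% of cells at 36, 48 and 72 hpf (59.3%, 63.0% and 65.6% before thinning), exactly 1 in 43.3%, 44.0% and 38.3%, and none in 14.1%, 12.3% and 14.0%. Thinning left out 2, 4 and 3 cells. In cells with at least 5 OR UMIs the leading receptor held a median of 96.2%, 97.8% and 94.1% of OR UMIs. The receptor or137-8 led more cells than any other, 14.5%, 6.66% and 12.8% of those in which a receptor held at least 80% of OR UMIs. As many as 50, 79 and 59 receptors led at least 1 cell, or 48, 72 and 56 when 500 cells were drawn from each library, and the 10 most frequent receptors led 76.8%, 40.2% and 61.1% of cells. Macrophage-like cells at 48 hpf, with a median of 26462 UMIs against 5667.5 in the mature cells, held 1 or more OR genes in 13.4% (10.7 to 16.5) of 559 cells at the same depth and in 77.6% before thinning, and more than 1 in 0.894% and 41.9%. A single stray OR transcript places an OSN with 1 receptor among cells with more than 1, so the shares above include such cells.

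Delta protocadherins were also counted per mature cell at the same depth. At 36 hpf 23.1% of cells had no delta protocadherin, 41.9% had 1, 25% had 2 and 10.1% had 3 or more. At 48 hpf these shares were 31.3%, 42.8%, 20.01% and 5.96%, and at 72 hpf 32.7%, 41.6%, 20.98% and 4.74%. Before thinning they were 3.68%, 15.4%, 25.2% and 55.8% at 36 hpf, 7.34%, 22.1%, 26.8% and 43.7% at 48 hpf, and 6.98%, 23.2%, 28.4% and 41.5% at 72 hpf. Macrophage-like cells at 48 hpf had 1 or more in 2.68% of cells at this depth and in 29.5% before thinning. There were 21 pairs of the 7 genes with enough cells, with both pcdh11 features joined. Of these 4 were found together more often than their single frequencies give in 3 of 3 libraries. They were pcdh10b with pcdh17 (mean odds ratio 1.67), pcdh7b with pcdh11 (1.36), pcdh19 with pcdh18b (1.3) and pcdh11 with pcdh19 (1.08). The odds ratio was below 1 in each library for 5 pairs, namely pcdh7b with pcdh19 (0.582), pcdh10b (0.602) and pcdh17 (0.742), and pcdh11 with pcdh10b (0.637) and pcdh17 (0.795). Some pairs lay near 1 in a library, and no intervals are given, so their direction is uncertain. At 36, 48 and 72 hpf pcdh11 with pcdh19 had 1.11, 1.01 and 1.1. For pcdh11 with pcdh10b the values were 0.336, 0.992 and 0.775, and with pcdh17 0.974, 0.658 and 0.785. The remaining 12 pairs were split, and chance alone puts 12.5% of pairs in each of these directions. Without doublet removal 2 pairs were above 1 in each library.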

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

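The alternatives with mature cells alone for summed delta protocadherins by age, those that take keratin-high cells out of the other cells, that without cells with microvillous marker UMIs for mature against immature cells, and those of the microvillous contrast were chosen after the results were seen. Among the main values 140 alternative values stayed within their counting interval, or within 1.5 times of a count, 43 moved and 1 reversed; among values of single genes and lists 2642 stayed, 83 moved, 175 fell below the threshold, 34 passed it and 17 reversed. Unless stated, the cause was not tested. Depth limits genes under about 5 CPM, families of few cells and the 31 immature cells at 48 hpf.

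The OSN-like share at 36 hpf was 28.7% with the looser cell filter, 27.9% without doublet removal, 33.6% at Leiden resolution 0.5, 27.9% with libraries clustered separately and 69.0% when cells needed only 3 detected ciliated markers. With the looser filter, resolution 0.5, separate clustering and the per-cell definition it was 18.1%, 23.7%, 22.7% and 51.3% at 48 hpf and 27.2%, 31.2%, 25.4% and 73.6% at 72 hpf. The per-cell definition takes in most keratin-high and microvillous cells.

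The summed delta protocadherins had log2 ratios for 48 over 36 hpf of -0.12 with TMM factors, -0.17 with separate clustering, -0.20 with the per-cell definition, -0.18 in mature cells and -0.17 with thinned cells. For 72 over 36 hpf these were -0.12, -0.28, -0.34, -0.28 and -0.29, and for 72 over 48 hpf TMM factors gave 0.0009, since TMM shifts every gene by 0.14. The log2 ratio of pcdh10b for 72 over 48 hpf was 0.011 with the per-cell definition and that of pcdh9 for 72 over 36 hpf 0.082 with thinned cells. The delta1 medians with members at 20 CPM or more were -0.088 and 0.022. With mature cells alone the list median of cilium assembly in OSN-like cells, 48 hpf over 36 hpf, turned to -0.016, and the list median of cilium assembly in OSN-like cells, 72 hpf over 36 hpf, to -0.0072. With TMM factors the list median of oxidative phosphorylation (nuclear) in OSN-like cells, 72 hpf over 48 hpf, turned to 0.0499. Other 72 over 48 hpf medians also lay within the TMM shift of 0.14, so their direction depends on the scaling. They were those of guidance ligands (-0.07), other adhesion genes (-0.03), clustered protocadherins (-0.08), cilium assembly (-0.08) and stress genes (-0.09).

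OSN-like against other cells gave 8 to 12 delta calls and 124 to 160 held-out calls with 1 library left out, and 8 to 13 and 124 to 160 over all alternatives. With the per-cell definition log2 fold changes reversed for pcdh1a (0.45), pcdh1b (0.995), pcdh20 (2.01 and 0.54), pcdh17 (-0.28), pcdh18a (-0.82), pcdh18b (-1.48), pcdhb (-0.14), epha2b (0.14), epha2a (0.66) and sema3ga (1.27), and that of pcdh1b was 0.12 without keratin-high cells and other olfactory neurons. Mature against immature cells gave 8 to 11 delta calls and 45 to 61 held-out calls with 1 library left out, and 45 to 65 held-out calls over all alternatives. Without cells that had UMIs of trpc2a, trpc2b or vmn2r1 it gave 9 and 51. Separate clustering was not run for it, because no immature class could be named at 36 and 72 hpf. The microvillous contrast gave 9 delta calls in each alternative, 37 to 48 held-out calls with 1 library left out and 35 with DESeq2.

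Pairs of gene and OR family numbered 964 with DESeq2, 128 without the library block, 1003 with all OR UMIs from the family and 1241 to 2820 with 1 library left out; delta pairs numbered 36 with DESeq2, 12 without the block and 43 to 51 with 1 library left out. Leaving out the block adds the spread between ages to the error. The profile correlation ranged from 0.542 with all OR UMIs from the family to 0.824. No paired analysis by replicate number was possible because each age had 1 library.

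At 1000 UMIs more than 1 OR gene was found in 32.4%, 34.1% and 37.5% of cells and 2 or more delta protocadherins in 14.0%, 10.8% and 9.69%, since fewer UMIs show fewer genes. Counting an OR gene from 2 UMIs gave 27.1%, 25.4% and 29.9%. Without doublet removal 2 pairs of delta protocadherins had odds ratios above 1 in each library.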

Other observations

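The microvillous contrast, the tests on keratin-high cells and the counts over other splits of the sums were chosen after the results were seen; the tests on age labels, immature cells and library batches were written before.

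Microvillous OSN-like cells, which signal through trpc2b and send axons to other parts of the bulb than ciliated OSNs, differed from ciliated OSN-like cells in most delta protocadherins tested. The class came from the olfactory neuron region, whose clusters were chosen by ciliated OSN markers. In that region a cluster with 5 of 8 microvillous markers raised also had ompb at 409 CPM and cnga4 at 282 CPM. Microvillous cells were higher than mature ciliated OSN-like cells of the same library in pcdh1a (3.32 ± 0.27, log2 with SE, 3 libraries), pcdh9 (1.71 ± 0.14), pcdh7a (1.70 ± 0.15) and pcdh10b (1.43 ± 0.11), the last at 251, 146 and 176 CPM against 71.7, 74.6 and 60.3 CPM at 36, 48 and 72 hpf. They were lower in both pcdh11 features (-0.76 each), pcdh7b (-0.75), pcdh18b (-0.66) and pcdh17 (-0.61), and 9 of 14 delta features passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, all 9 also when adjusted over the list alone. Among 135 held-out genes 40 were higher and 15 lower, and 61 passed when adjusted over the list alone. The adhesion gene dscamb, a homophilic receptor of the immunoglobulin family, was at 62.8, 59.97 and 83.8 CPM against 5.03, 4.48 and 1.81 CPM (4.16 ± 0.23), and kirrel3a, a sorter of vomeronasal axons in mammals, was higher by 1.48. Guidance receptors gave 8 higher and 4 lower of 26, with nrp2a at 1.96, plxnb1a at 1.11 and nrp2b at 0.92, ligands 7 and 3 of 23, with sema6e at 1.81, adhesion genes 11 and 2 of 38, other cadherins 5 and 1 of 15, and clustered protocadherins 5 and 0 of 19. Subcluster 8 held most microvillous cells at 36 hpf (194) and subcluster 5 at 48 and 72 hpf (187 and 199). The count of 55 was 45, 48 and 37 without the 36, 48 or 72 hpf library and 35 with DESeq2.

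Several groups of sorted cells stood outside the OSN-like class, and with 1 library per age a group found mostly in 1 library may be that library and not a type. A subcluster led by ora3, emx1 and glulc held 2.38%, 0.737% and 2.66% of cells at 36, 48 and 72 hpf, and a subcluster led by taar13b, taar12i and tbr1b 0.0267%, 1.57% and 1.43%. A cluster led by gnrh3, the neuropeptide of terminal nerve neurons, held 3.15%, 0.515% and 1.33%. No name was given to this cluster. It had 10 of 14 endothelium markers raised and krt4 at 1089 CPM, so its cells cannot be read as terminal nerve neurons alone. Of clusters led by retina genes some were mostly of the 48 hpf library, with 1, 357 and 9 cells for vsx1 and gnb3a, 5, 202 and 13 for crx and nr2e3, and 9, 210 and 48 for pou4f2 and isl2b. A cluster led by the retinal progenitor genes foxn4, atoh7 and rx1 was found in all libraries, with 147, 335 and 208 cells. Photoreceptor-like cells were 184 at 48 hpf, with rho at 1652 CPM, opn1lw2 at 2320 CPM and arr3a at 1594 CPM, and 0 of 4890 at 72 hpf, which allows a share of up to 0.0613%. Multiciliated-like cells were 2.08%, 2.84% and 4.13%, radial glia-like cells 3.34%, 2.34% and 2.41%, and mesenchyme-like cells 1.23%, 2.37% and 1.49%. A cluster of cycling progenitor-like cells held 6.60%, 2.84% and 4.56%; it had 12 of 13 cycling markers raised but also 7 of 11 radial glia or neural progenitor markers, and was led by her2, sox19a and her4.2, so it is not a type apart from neural progenitors. The cluster genes named here were chosen after their values were seen.

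In the library labelled 48 hpf OR genes and OSN markers were highest and the immature share lowest; the OR ratio of 48 over 36 hpf was 2.21 as a median over genes but 0.71 over all OR UMIs, and the 10 most frequent receptors led 76.8%, 40.2% and 61.1% of cells, so the median largely reflects a wider spread of receptors. Fewer immature cells are argued against as the whole cause, since in mature ciliated OSN-like cells alone the values were 2.03 and 0.52 (0.50 to 0.53), but part of the ratio over all OR UMIs stays open to them. A swap of the 48 and 72 hpf labels cannot be told apart from correct labels. The levels of lin28a, lin28b, igf2bp1, igf2bp3 and hmga2, which embryos lose with age, were summed for this. Their sum was lower in the library labelled 48 hpf in 3 of 5 cell classes and higher in the others. As log2 of 48 over 72 hpf it was -0.24 in cycling progenitor, -0.57 in radial glia and -0.73 in mesenchyme cells. In central nervous system neuron cells it was 0.15 and in OSN-like cells 0.09. The radial glia and neuron classes mix clusters in shares that differ between libraries. Within radial glia the ratio was -0.03 (-0.24 to 0.18) in cluster 17 and -0.85 (-1.23 to -0.45) in cluster 25. Cluster 25, with 15 cells at 72 hpf, thus goes with a swap. Within neurons it was 0.03 (-0.12 to 0.18) in cluster 3 and 0.45 (-0.20 to 1.19) in cluster 15, which had 6 cells at 72 hpf. By gene, looked at after the values were seen, lin28a goes with a swap. It was at -1.53, -2.26, -3.28 and -2.98 in the cycling progenitor, radial glia, mesenchyme and neuron classes. In clusters 17 and 3 it was at -1.85 and -2.39. Against a swap go hmga2 in cycling progenitor (0.69) and radial glia cells (0.95) and igf2bp3 in OSN-like cells (0.29). Within radial glia hmga2 was at 1.425 in cluster 17 and -0.57 (-1.41 to 0.38) in cluster 25. The value of igf2bp3 in neurons, 0.71, mixes clusters. It was 0.17 (-0.14 to 0.49) within cluster 3 and so does not go against a swap. In mesenchyme hmga2 was lower (-0.49), and igf2bp1 makes up the greatest part of the sum. The 184 photoreceptor-like cells with rho, which differentiating rods express, in the library labelled 48 hpf and 0 in that labelled 72 hpf go with a swap, but retina enters a library only as far as the dissection and sort take it along, which was not tested, and a difference between ages stays open and untested.

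A set of 17 ribosomal protein, oxidative phosphorylation and mitochondrial genes was low in the library labelled 36 hpf, among them rpl26 (15.04, 236 and 247 CPM), mt-atp8 (4.15, 25.7 and 20.1 CPM) and cox7c (215, 768 and 663 CPM). They were picked from 172 genes of the 3 lists by a log2 ratio of 72 over 36 hpf of at least 1 in OSN-like cells. Over all 172 genes the median ratio was 0.10 in OSN-like cells and 0.09 to 0.12 in the 5 other classes compared below. A difference between library batches was tested on 5 other cell classes, keratin-high cells among them. All 17 genes were higher at 72 than at 36 hpf in each of them, and the lowest class median of the log2 ratio was 1.098, against 1.22 in OSN-like cells. This is in line with a property of the library that all its cells share, such as its preparation, and a difference between ages in all cell types remains open and untested.

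Keratin-high cells with OSN transcripts made up 26.9%, 16.3% and 32.0% of the 3 libraries, with a median of 27421, 27399 and 28098 UMIs. Free RNA from lysed OSNs stays open. In keratin-high cells ompb was at least 38.8 times its level in macrophage-like cells of the same library. But the class was defined by clusters with ompb at 100 CPM or more. Macrophage-like cells had 3.42, 8.505 and 1.88 CPM, from 18, 559 and 17 cells. A high fold was thus set by that definition, and the test cannot decide. For barcodes that hold an OSN and another cell, the predicted values were found, but with limits. Over 511 OSN genes the ratio of their level to that in OSN-like cells was narrow, with quartiles of 0.414 and 0.531 and a quotient of 1.28. Its median was 0.467. OSN-like cells had a median of 6726.5, 5695 and 5718 UMIs, so 1 such cell would make up a smaller part of these barcodes. Among barcodes with at least 20 OR UMIs, 2 or more families each held over 10% of them in 54.2%, 53.6% and 64.7% of keratin-high barcodes (661, 834 and 1258), against 36.5%, 25.6% and 38.2% of OSN-like cells (838, 1190 and 1013). A cell without OR genes adds no second family to 1 OSN, so that pairing would not by itself give these higher shares. The doublet rate assumed for this chemistry was 3.11%, 6.13% and 4.09% of filtered cells. At that rate chance meeting in droplets would give fewer keratin-high barcodes than were found. That rate was not measured in these libraries. No biological explanation was tested, nor whether such cells adhered before or during the sort.

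For the tested contrasts the 6 sums allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 144 held-out genes for OSN-like against other cells and 61 for mature against immature cells, with 0 as the highest of the other splits in both, 2329 pairs of gene and family over the OR families with 35 as the highest other, and 55 for microvillous against ciliated cells with 0. Each other split mixes the real classes in both of its groups. Their difference then adds to the error, so the design favours low counts there and no conclusion is drawn from them.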
